A study of Mus musculus with 50 samples.

How the data were processed

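RNA was sequenced from 50 libraries of RAW264.7 cells, a mouse macrophage line. The lines carried an empty vector (control cells), a knockout of SGK1, a knockout of SGK3, or a double knockout of SGK1 and SGK3. Cells were at rest or stimulated for 2 h with 10 µg/mL DMXAA, an agonist of mouse STING. A further group of control cells was given 500 nM of Sanofi-14h, an inhibitor of SGK kinases, for 2 h before DMXAA. The libraries were poly-A selected, per the labels. The labels mention a vehicle but do not say which control libraries received it, and they name 1 line per genotype without saying whether each was a clone.

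The authors aligned reads with STAR 2.7.9a and quantified genes with StringTie 2.2.0 on GRCm39, per the labels. The annotation was GENCODE M27, as named on the deposited tables. The deposited expected counts are estimated counts per gene for 55416 genes; how the authors counted and filtered was not stated. They were rounded to whole numbers on loading, which leaves values that were already whole unchanged. Among protein-coding values from 1 to 16, 17.5% were 4, the most frequent value. For the floors below, 1 read pair was therefore taken as 4 counts. The labels do not state this unit and the values leave it in doubt, since the share at 8 (8.08%) was close to that at 7 (7.84%), and that at 12 (5.35%) to that at 11 (5.23%). The counts carry no information on strand or on reads shared between paralogs, so members of the Ifit, Oas, Gbp and H2 families may share reads. The deposited TPM values, made by the authors, were used for one alternative. All coordinates are on GRCm39.

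Libraries fall into 3 batches by the numbers, letters or suffix in their names. Batch b1 held 26 libraries, b2 held 20 and b3 held 4. Batch b3 was left out of the fit because it held 4 libraries, 1 of them (J) with a title and a treatment field that differ. The titles of its libraries J, S, V and W are marked as reruns, and these letters are missing from the series of b2. Batch b3 may therefore not be separate from b2 as an experiment. The remaining 46 libraries were fitted together in edgeR 4.0.16 under R 4.3.3. Of the 55416 genes, 21885 are annotated as protein coding, and filterByExpr left 18315 genes of any type for testing. Counts were scaled by TMM. Each group of each batch had its own coefficient, and contrasts were tested with edgeR's robust quasi-likelihood F test, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Of the 16 comparisons, the DMXAA response in control cells and the double knockout with DMXAA were the mean of the b1 and b2 contrasts. The other comparisons used 1 batch each, with the control cells of that batch. Levels are CPM (counts scaled for depth) on TMM-scaled library sizes, as mean ± SD, and fold changes are log2 ± SE. The p-values measure only the spread between these samples, since nothing in the labels says that replicates were separate cultures. That spread is 1 estimate per gene, shared by all groups of both batches.

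Depth was 57859509 to 112007140 counts per library. A gene with no count in a group was given a floor of 3 read pairs, or 12 counts, per library, which came to between 0.132 and 0.188 CPM by group. Folds against such groups are given as lower bounds from that floor, and any other group of such a gene that lay below its floor was raised to it. The bounds rest on the assumed unit, and would be higher with fewer counts per pair and lower with more. Floors cover counting error only. On simulated data with 100 genes changed at each size among 18315, the test recovered 87% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1 for the SGK3 knockout with DMXAA. For the SGK1 knockout it recovered 47% and 94% at rest, and 74% and 94% with DMXAA. False calls numbered 4, 3 and 7, a raised list of 25 genes was called each time, and 0 of 20 unchanged lists were called. The simulation used the same spread for both batches, independent genes and no length trend. It therefore does not give the rate of false calls in b2 or for lists of genes that move together.

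Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the genes of a list move one way on balance without comparing them with other genes. P-values of lists were adjusted over the 19 lists of a comparison. The 18 lists written from general knowledge were interferon and IRF3 early response, interferon-stimulated genes, NF-kB and inflammatory cytokines, immediate early genes, STING pathway components, SGK and PI3K pathway components, FOXO target genes, ATF4 and amino acid response, endoplasmic reticulum unfolded protein response, sterol synthesis and SREBP2 targets, glycolysis and hypoxia, lysosome and TFEB targets, cell cycle, p53 target genes, alternative activation, osteoclast markers, macrophage identity and antigen presentation. A further list held markers of other cell types.

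The comparisons, lists, and rule for naming genes were fixed before the data were examined. The rule names Sgk1, Sgk2 and Sgk3 throughout. For each comparison of 2 conditions it adds the 6 genes with the largest rise and the 6 with the largest fall among those past the threshold with a mean of at least 5 CPM in the higher group, a symbol that is not a Gm number, a Rik clone name or an identifier, and every library of one group above every library of the other. For each list called by camera it adds up to 3 members with the smallest p in the list's direction and 1 against it. For interactions and for knockout against knockout it adds the 3 genes with the smallest p in each direction. Genes outside the rule are marked as chosen after their values were seen. A 2-fold change is a log2 fold change of 1.

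The alternatives fixed beforehand were relative log expression (RLE) scaling, no filter on low counts, DESeq2 1.42.0, limma-trend on log2 TPM with a pseudocount of 1, a fit of the groups compared alone, a replicate block, each batch alone, b3 added, a stricter fold limit for genes responsive to DMXAA, overlaps over genes of at least 5 CPM, and leaving out each library in turn. After the data were seen, 5 were added. These were removal of a per-library trend with transcript length and GC content, the replicate block together with that removal, omission of b2 libraries whose log2 CPM rose by more than 0.1 per doubling of transcript length, counts divided by 4, and another dispersion trend. Quality measures included the share of the top 20 genes. Groups of 4 and 5 libraries were searched for single distant values with Dixon's ratio, and other splits of the libraries were fitted to count genes past the threshold by regrouping.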

Results

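Gene expression was measured by RNA sequencing in 50 libraries of the mouse macrophage line RAW264.7. Batch b1 held control cells (empty vector) at rest (n = 3), with DMXAA (n = 5) and with inhibitor and DMXAA (n = 5), the SGK3 knockout at rest (n = 3) and with DMXAA (n = 5), and the double knockout with DMXAA (n = 5). Batch b2 held control cells at rest (n = 3) and with DMXAA (n = 4), the SGK1 knockout at rest (n = 3) and with DMXAA (n = 4), and the double knockout at rest (n = 3) and with DMXAA (n = 3). The 4 libraries of b3 entered no fit but an alternative with b3 added, in which control library J, whose title and treatment field differ, was taken as treated with DMXAA. Values of library J are also described further below. Depth ranged from 57859509 to 101068327 counts in b1, from 63461414 to 112007140 in b2 and from 76295599 to 86754670 in b3.

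Between 18100 and 19700 genes had a count in the libraries of b1, and between 15000 and 17800 in those of b2. Ribosomal protein genes took 6.49% to 9.25% of counts in b1 and 2.69% to 6.77% in b2, and the 20 most abundant genes took 9.08% to 12.8% and 10.0% to 12.3%. None of 71 pairs of replicates was identical, and their Spearman correlations across genes ran from 0.959 to 0.986. Genes are not independent replicates, so such correlations describe similarity only. In b2, log2 CPM rose with transcript length by more than 0.1 per doubling, relative to the batch mean, in 6 libraries. These were SGK1 knockout rest libraries E (0.25) and F (0.37), SGK1 knockout DMXAA libraries P (0.20) and R (0.12), double knockout DMXAA library X (0.23) and double knockout rest library H (0.11).

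**Figure D1:**
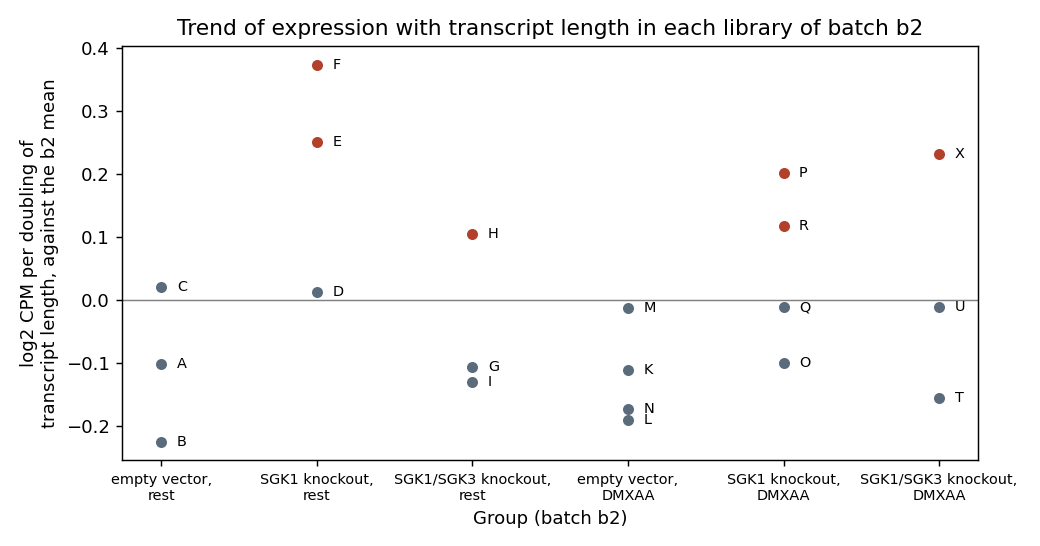
Change of log2 CPM per doubling of transcript length, relative to the b2 mean, for each library of b2. Red marks the libraries above 0.1, the steepest being SGK1 knockout rest library F at 0.37.

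Sgk1 (ENSMUSG00000019970.16, chromosome 10, 21758083 to 21875802) encodes SGK1. In b1 control cells Sgk1 was at 1.59 ± 0.318 CPM at rest (SD, n = 3) and 50.5 ± 3.15 with DMXAA (n = 5). In b2 it was at 2.16 ± 1.01 (n = 3) and 35.1 ± 6.52 (n = 4). In the SGK1 knockout it stood at 0.667 ± 0.809 CPM at rest (n = 3; 0.252, 0.15 and 1.6 in libraries D, E and F, the last above the 1.06 of control library C) and 4.25 ± 2.33 with DMXAA (n = 4). In the double knockout it stood at 0.622 ± 0.218 at rest in b2 (n = 3), and with DMXAA at 4.78 ± 1.11 in b1 (n = 5) and 2.46 ± 0.679 in b2 (n = 3). With DMXAA, Sgk1 was lower than in control cells in the SGK1 knockout (log2 fold change -3.05 ± 0.37 SE, adjusted p = 5.56e-08), the double knockout (-3.62 ± 0.28, adjusted p = 4.46e-13), the SGK3 knockout (-1.23 ± 0.31, adjusted p = 0.00485) and control cells with inhibitor (-2.13 ± 0.32, adjusted p = 6.7e-06). The SGK3 knockout had 21.6 ± 2.23 CPM with DMXAA (n = 5), and inhibitor-treated control cells had 11.5 ± 1.98 (n = 5). At rest, Sgk1 was lower in the SGK1 knockout (-1.66 ± 0.48, adjusted p = 0.0095) and the double knockout (-1.80 ± 0.48, adjusted p = 0.0148). The former call (Sgk1, SGK1KO vs WT at rest) ended without control rest library A (adjusted p = 0.0674) or SGK1 knockout rest library E (0.0812), and the latter (Sgk1, dKO vs WT at rest) without double knockout rest libraries G (0.0738) or H (0.0991), or control rest libraries A (0.121) or B (0.0515). Both calls also ended in a fit of the groups compared alone, with adjusted p = 0.257 and 0.0781, and with limma on TPM, with 0.26 and 0.387.

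Sgk3 (ENSMUSG00000025915.15, chromosome 1, 9868332 to 9971070) encodes SGK3. Its group means lay between 89.1 and 118 CPM in b1 and between 123 and 129 CPM in b2, edited lines included. Sgk3 did not differ from control cells past the threshold in the SGK3 knockout at rest (log2 fold change -0.08 ± 0.08, adjusted p = 0.899) or with DMXAA (0.05 ± 0.06, adjusted p = 0.748), nor in the double knockout at rest (0.06 ± 0.08, adjusted p = 0.832) or with DMXAA (0.11 ± 0.05, adjusted p = 0.0681). The double knockout value with DMXAA was a mean over unlike batches. In b1 Sgk3 was at 118 ± 1.34 CPM against 100 ± 4.39 in control cells, with every double knockout library above every control library. In b2 it was at 128 ± 21.7 against 128 ± 8.62. Counts per gene do not show the edited site. Sgk3 passed with DMXAA in the SGK3 knockout (0.23 ± 0.07, adjusted p = 0.0139), a call (Sgk3, DMXAA response in SGK3KO) that ended without SGK3 knockout rest library 2 (0.0611) or 3 (0.0524), with limma on TPM (0.537) and with the length and GC trend removed (0.136), or with a replicate block besides (0.147). Sgk2 had between 0 and 12 counts per library and was not tested.

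**Figure D2:**
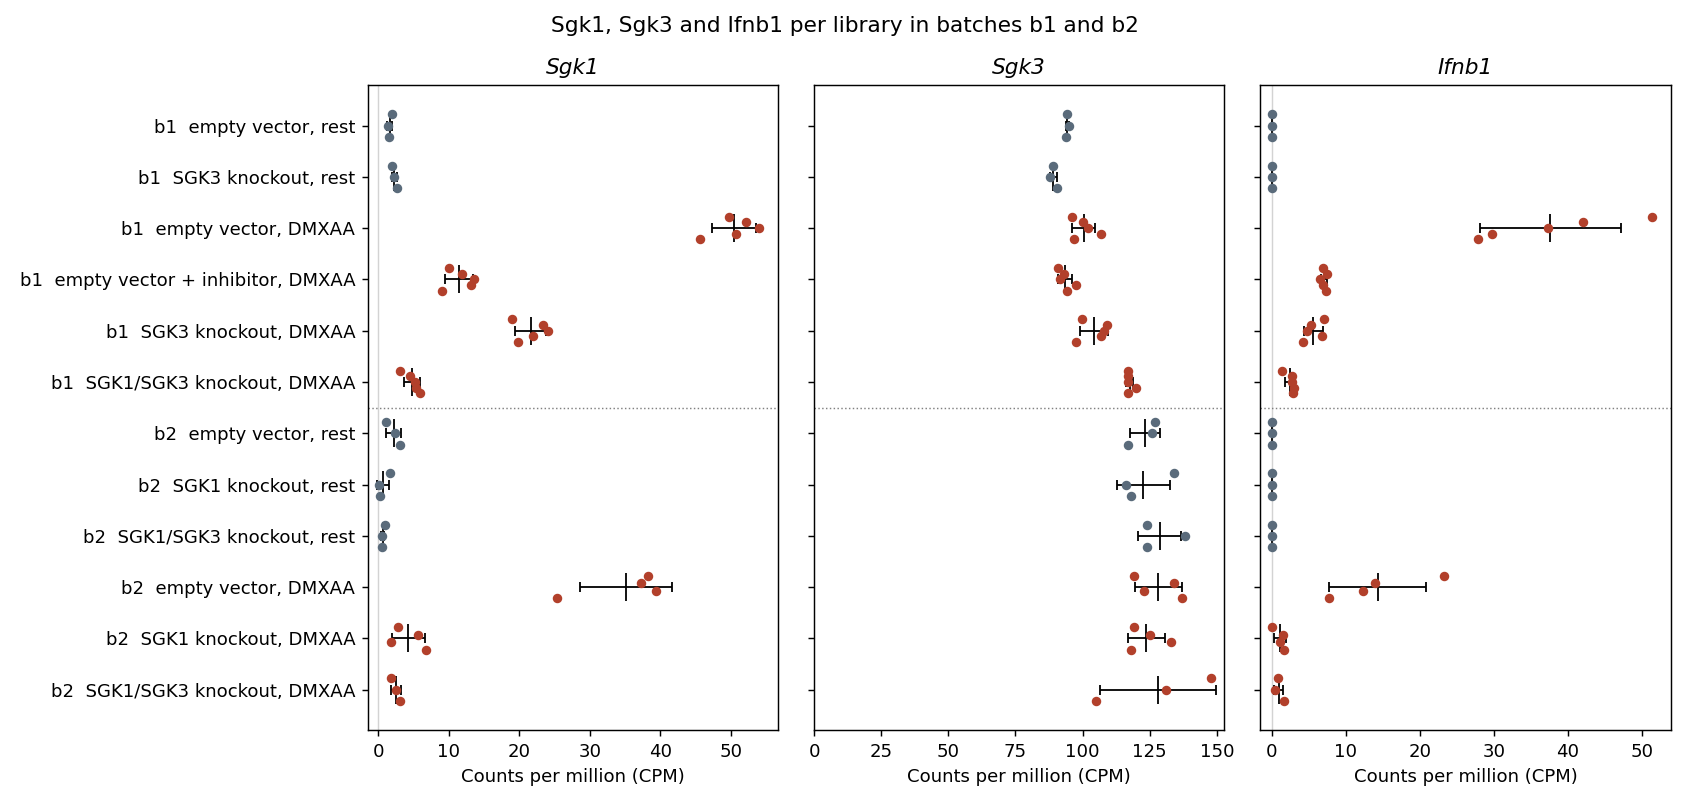
CPM of Sgk1, Sgk3 and Ifnb1 for each library of b1 and b2, by batch and group, with group means and SD. With DMXAA, Sgk1 means were 50.5 and 35.1 CPM in control cells, and 4.25 CPM in the SGK1 knockout, while Sgk3 means lay between 93.4 and 128 CPM in the DMXAA groups of b1 and b2.

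The DMXAA response in control cells shows what STING stimulation does within 2 h. It changed 4209 genes, 2219 up and 1990 down, of which 668 rose and 277 fell at least 2-fold. In b1 alone 3864 genes passed (1978 up, 1886 down), in b2 alone 1443 (878 up, 565 down), and the response differed between batches in 591 genes. Ifnb1 (ENSMUSG00000048806.5, chromosome 4, 88440262 to 88441011), which encodes interferon beta, had no count at rest in any library of either batch and reached 37.7 CPM in b1 (27.9 to 51.3, n = 5) and 14.3 CPM in b2 (7.71 to 23.3, n = 4), at least 134-fold higher. Rsad2 (ENSMUSG00000020641.17, chromosome 12, 26492745 to 26506451), which encodes the antiviral protein viperin, rose from 3.44 ± 1.7 to 1670 ± 130 CPM in b1 and from 3.38 ± 0.627 to 319 ± 65.6 in b2 (log2 fold change 7.74 ± 0.25, adjusted p = 3.36e-24). The chemokine gene Cxcl10 rose by 6.05 ± 0.22 and Tnf by 3.69 ± 0.14, and the immediate early gene Egr1 rose by 4.15 ± 0.12 (adjusted p = 7.68e-23, 6.43e-23 and 3.94e-27). Neat1, a long noncoding RNA, fell by 3.67 ± 0.25 and Arrdc3 fell by 2.34 ± 0.21 on the log2 scale (adjusted p = 2.31e-14 and 2.04e-12). Every gene named for the size of its change between 2 conditions, here and in the comparisons that follow, had every library of one group above every library of the other within each batch used, which chance gives for 10% of genes with 3 libraries against 3.

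Of 18 genes of the interferon and IRF3 early response list, 17 rose and 1 did not pass, and 17 rose adjusted over the list alone (median log2 fold change 3.96, or 3.68 with genes at 0 held at their bounds, adjusted p = 3.98e-31). The medians were 5.45 in b1 and 2.98 in b2, or 4.54 and 2.71 with bounds. Of 41 interferon-stimulated genes, 36 rose and 5 did not pass, with 39 up adjusted over the list alone (median 0.89, adjusted p = 6.7e-28; 1.28 in b1 and 0.47 in b2). NF-kB and inflammatory cytokines had 20 of 31 genes up, 1 down and 10 not passing, with 21 up and 1 down adjusted over the list alone (median 1.10, or 0.51 with bounds, adjusted p = 1.01e-15). Immediate early genes had 19 of 25 up, 2 down and 4 not passing, with 20 up and 2 down adjusted over the list alone (median 0.95, adjusted p = 1.81e-15). These 4 calls held with an estimated correlation. Sterol synthesis and SREBP2 targets had 2 genes up, 15 down and 7 not passing, the same numbers adjusted over the list alone (median -0.22, adjusted p = 3.96e-05, adjusted p = 0.0931 with an estimated correlation). By fry, the early response list moved up on balance (adjusted p = 1.01e-23).

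The DMXAA responses of the edited lines show which part of the response each line kept. The SGK3 knockout changed 3030 genes (1573 up, 1457 down; n = 3 and 5), the SGK1 knockout 4405 (2301 up, 2104 down; n = 3 and 4) and the double knockout 2564 in b2 (1365 up, 1199 down; n = 3 and 3). These counts do not rank the lines, since fits of the groups compared alone gave 5323, 751 and 477. The count for DMXAA response in SGK1KO was 2790 without rest library F and 1987 without the libraries of steep length trend, which left 1 library at rest, the spread coming from other groups. Ifnb1 was at least 30.0-fold higher in the SGK3 knockout, from no count to 5.64 CPM. Rsad2 rose by 5.98 ± 0.36 in the SGK1 knockout, from 0.439 to 27.8 CPM (adjusted p = 2.35e-15). It also rose in the SGK3 and double knockouts, to 36.5 and 9.87 CPM (adjusted p = 4.19e-17 and 6.06e-14), from means of 0.0921 and 0.0681 CPM, too low to measure a fold. Tnf rose by 3.32 ± 0.19, 3.96 ± 0.20 and 2.95 ± 0.20 (adjusted p = 8.75e-17, 2.16e-18 and 1.1e-14). The early response list was called up in each line, with 15, 12 and 12 of 18 genes up and none down, the other 3, 6 and 6 not passing (15, 12 and 12 up adjusted over the list alone, with 1 down in the SGK1 knockout). Its medians were 5.54, 3.68 and 3.53, or 5.19, 3.24 and 3.33 with bounds (adjusted p = 6.69e-34, 2.07e-16 and 1.04e-20), and the calls held with an estimated correlation. Interferon-stimulated genes were called up in the SGK3 knockout (29 of 41 up, 12 not passing, 32 up adjusted over the list alone; median 0.91, or 0.83 with bounds, adjusted p = 2.73e-30). In the SGK1 knockout 14 rose, 13 fell and 14 did not pass, with 15 up and 17 down adjusted over the list alone (median -0.24, or -0.22 with bounds, adjusted p = 0.736). In the double knockout 13 rose, 6 fell and 22 did not pass, with 16 up and 9 down adjusted over the list alone. The test gave a rise (adjusted p = 0.0152, adjusted p = 0.465 with an estimated correlation, 0.0936 in a fit of the groups alone), while the fitted median was 0. With bounds the median was 0.16. That value is the one given to a gene below its floor in both groups (0.166 and 0.148 CPM), so it measures no change of the list.

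In the SGK1 knockout, lysosome and TFEB targets had 21 of 33 genes up, 1 down and 11 not passing (23 and 1 adjusted over the list alone; median 0.36, adjusted p = 9.42e-12). In the double knockout they had 18 up, 2 down and 13 not passing (22 and 2 adjusted over the list alone; median 0.27, adjusted p = 5.65e-16). Cell cycle genes fell in the double knockout, with 20 of 36 down, none up and 16 not passing (23 down adjusted over the list alone; median -0.26, adjusted p = 1.77e-12), among them the cyclin gene Ccnd1 at -1.13 ± 0.07 (adjusted p = 1.31e-15). The lysosome and cell cycle calls held with an estimated correlation. In the SGK1 knockout 15 cell cycle genes fell, 3 rose and 18 did not pass, with 16 down and 3 up adjusted over the list alone (median -0.15, adjusted p = 0.000182, adjusted p = 0.0608 with an estimated correlation). The p53 target genes were called up in the SGK3 knockout, with 6 of 23 up, 1 down and 16 not passing (6 and 3 adjusted over the list alone; median 0.24, adjusted p = 0.0183, adjusted p = 0.101 with an estimated correlation; 0.061 in a fit of the groups alone). ATF4 and amino acid response genes were called up in the SGK1 knockout, with 11 of 25 up, 1 down and 13 not passing (12 and 1 adjusted over the list alone; median 0.26, adjusted p = 0.002, adjusted p = 0.305 with an estimated correlation). Bbc3, which encodes the apoptosis regulator PUMA, rose by 2.87 ± 0.16 in the SGK3 knockout and 3.11 ± 0.17 in the double knockout (adjusted p = 2.38e-17 and 2.94e-17).

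The SGK3 knockout was compared with control cells at rest (n = 3 and 3, b1) for how the lines differed without stimulation. Each genotype is named as 1 line, so differences between lines from other sources are included in this and the other comparisons of lines. The count was 882 genes, 512 up and 370 down, against 2316 in a fit of the groups compared alone and 1359 without the steep libraries of b2 (SGK3KO vs WT at rest). Maoa (ENSMUSG00000025037.7, chromosome X, 16485937 to 16554057), which encodes monoamine oxidase A, had no count in control cells and was at least 153-fold higher. Plod2 (ENSMUSG00000032374.15, chromosome 9, 92424276 to 92490481), which encodes a lysyl hydroxylase, was at 10.5 CPM in control cells and had no count in the knockout, at least 56.1-fold lower. Ptprk (ENSMUSG00000019889.11, chromosome 10, 27950816 to 28473393) was at least 241-fold higher, a call that ended with DESeq2 (adjusted p = 0.13), and Adgrl2 at least 42.7-fold lower. Gpnmb rose by 4.26 ± 0.26 (adjusted p = 2.47e-16), from 1.92 to 36.9 CPM. Interferon-stimulated genes had 36 of 41 down, none up and 5 not passing, with 38 down adjusted over the list alone (median -2.14, or -1.99 with bounds, adjusted p = 9.69e-102). Early response genes had 10 of 18 down and 8 not passing, with 13 down adjusted over the list alone (median -2.50, adjusted p = 1.68e-25). Rtp4 fell by 4.39 ± 0.26 and Cmpk2 fell by 4.57 ± 0.34 (adjusted p = 1.02e-15 and 1.29e-12). Antigen presentation genes had 8 of 23 down and 15 not passing, with 15 down adjusted over the list alone (median -0.44, adjusted p = 1.1e-14). Sterol synthesis and SREBP2 targets had 14 of 24 up and 10 not passing, with 17 up adjusted over the list alone (median 0.31, adjusted p = 2.1e-16). These 4 calls held with an estimated correlation, as did those of the unfolded protein response (7 of 20 down, median -0.21, adjusted p = 3.92e-08) and of lysosome and TFEB targets (11 up and 3 down of 33, median 0.21, or 0.19 with bounds, adjusted p = 2.95e-09).

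With DMXAA (n = 5 and 5, b1) the same pair of lines shows whether the stimulated state differed. The count was 1986 genes, 1127 up and 859 down, of which 167 and 280 changed at least 2-fold. It was 3480 in a fit of the groups compared alone and 3050 without the steep libraries of b2 (SGK3KO vs WT with DMXAA). Rsad2 was at 1670 ± 130 CPM in control cells and 36.5 ± 5.47 in the SGK3 knockout (log2 fold change -5.52 ± 0.24, adjusted p = 2.73e-19). Ifnb1, chosen after its values were seen, was at 37.7 and 5.64 CPM (-2.74 ± 0.49, adjusted p = 0.000193). Cmpk2 fell by 5.15 ± 0.23 and Usp18 fell by 3.47 ± 0.23 (adjusted p = 4.18e-19 and 9.17e-15). Sting1 (ENSMUSG00000024349.11, chromosome 18, 35866732 to 35873607), which encodes the receptor of DMXAA, fell from 34.1 ± 2.32 to 22.5 ± 1.69 CPM (-0.60 ± 0.08, adjusted p = 3.88e-07), and Cgas fell from 170 ± 7.71 to 95.4 ± 5.91 CPM (-0.84 ± 0.05, adjusted p = 1.57e-16). The early response list had 14 of 18 genes down, none up and 4 not passing, with 16 down adjusted over the list alone (median -1.61, or -1.44 with bounds, adjusted p = 7.86e-26). Interferon-stimulated genes had 38 of 41 down and 3 not passing, with 40 down adjusted over the list alone (median -1.84, adjusted p = 1.77e-89). Antigen presentation genes had 17 of 23 down and 6 not passing, with 18 down adjusted over the list alone (median -0.58, adjusted p = 1.04e-17). These calls held with an estimated correlation. STING pathway components had 2 of 25 up, 5 down and 18 not passing, the same numbers adjusted over the list alone (median -0.04, adjusted p = 0.0294, adjusted p = 0.162 with an estimated correlation; 0.0677 without SGK3 knockout DMXAA library 2). NF-kB and inflammatory cytokines were not called (3 up, 7 down and 21 not passing of 31; 4 and 8 adjusted over the list alone; median -0.45, adjusted p = 0.0501). By fry, the early response and interferon-stimulated lists moved down on balance (adjusted p = 1.02e-13 and 1.07e-18).

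The interaction asks whether the DMXAA response itself differed between the SGK3 knockout and control cells. It differed in 36 genes, 16 up and 20 down, but the count depended on the setting. It was 157 in a fit of the groups compared alone, 103 with DESeq2, 81 with limma on TPM, 92 with the length and GC trend removed and 113 without the steep libraries of b2. Rtp4 had a higher log2 fold change in the knockout by 3.06 ± 0.30 (adjusted p = 3.46e-08), going from 1.94 to 88.2 CPM against 40.8 to 221 CPM in control cells. Irf1, which encodes a transcription factor of interferon responses, had a lower one (-1.96 ± 0.23, adjusted p = 8.56e-07), going from 13.4 ± 1.27 to 22 ± 0.92 CPM against 19.2 ± 1.52 to 122 ± 9.25. The interaction was negative for immediate early genes, with 3 of 25 down, none up and 22 not passing, and 9 down adjusted over the list alone (median -0.55, adjusted p = 3.49e-12). It was also negative for sterol synthesis and SREBP2 targets, with no gene of 24 passing and 10 down adjusted over the list alone (median -0.21, adjusted p = 1.71e-14). Both calls held with an estimated correlation. A call up for list interferon and IRF3 early response, SGK3KO difference in DMXAA response, came with 1 of 18 genes up and 17 not passing (5 up adjusted over the list alone; median 0.27, adjusted p = 0.00082, adjusted p = 0.308 with an estimated correlation), a call that ended without control rest library 1 (0.0709) and turned with limma on TPM (adjusted p = 1.44e-08). The count was 23 without control rest library 3, 22 and 20 without SGK3 knockout rest libraries 1 and 2, and 23 without SGK3 knockout DMXAA library 5.

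The SGK1 knockout was compared with control cells at rest (SGK1KO vs WT at rest, n = 3 and 3, b2) for how these lines differed without stimulation. The count was 4760 genes, 2089 up and 2671 down, and 255 in a fit of the groups compared alone. It was 2599 with the length and GC trend removed. Without the steep libraries it was 653, with 1 knockout library left and the spread taken from other groups. Without 1 library it was 1927 (control B), 3143 (SGK1 knockout E) and 1879 (SGK1 knockout F). Maoa was at 0.0576 CPM in control cells (at most 0.173) and 24.8 to 29.0 CPM in the groups of the edited lines, with at least 20.8 CPM in each SGK1 knockout library, F included. Zfp334, which encodes a zinc finger protein, was at least 46.4-fold higher, Plod2 at least 52.2-fold lower and Adgrl2 at least 40.7-fold lower. Cmpk2 fell by 3.27 ± 0.29 and Rtp4 fell by 3.40 ± 0.24 (adjusted p = 1.85e-10 and 2.09e-13). Dusp4, which encodes a phosphatase of MAP kinases, fell by 2.14 ± 0.15 (adjusted p = 1.21e-14). Interferon-stimulated genes had 35 of 41 down, none up and 6 not passing, with 36 down adjusted over the list alone (median -1.42, or -1.40 with bounds, adjusted p = 5.39e-36). In the early response list, 11 of 18 were down and 7 did not pass, with 12 down adjusted over the list alone (median -1.91, adjusted p = 2.87e-10). Both of these calls held with an estimated correlation. Antigen presentation genes had 16 of 23 down and 7 not passing, with 17 down adjusted over the list alone (median -0.62, or -0.60 with bounds, adjusted p = 2.87e-10, adjusted p = 0.0564 with an estimated correlation). SGK and PI3K pathway components had 13 of 27 up, 2 down and 12 not passing, with 14 up and 4 down adjusted over the list alone (median 0.26, adjusted p = 0.00125, adjusted p = 0.397 with an estimated correlation); with the length and GC trend removed the direction turned (adjusted p = 0.379).

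With DMXAA (n = 4 and 4, b2) the SGK1 knockout differed from control cells in 3827 genes, 1727 up and 2100 down, of which 315 and 539 changed at least 2-fold. The count for SGK1KO vs WT with DMXAA was 1556 in a fit of the groups compared alone, 2373 with b3 added and 2300 without the steep libraries. Maoa was at least 161-fold higher, Zfp334 at least 29.8-fold higher and Plod2 at least 71.0-fold lower. Rsad2 was at 319 ± 65.6 CPM in control cells and 27.8 ± 7.04 in the knockout (-3.52 ± 0.25, adjusted p = 1.18e-13), and Ifnb1, chosen after its values were seen, at 14.3 and 1.11 CPM (-3.70 ± 0.58, adjusted p = 3.01e-05). Usp18, which encodes a protease that removes ISG15, fell by 4.36 ± 0.27 and Oas3 fell by 3.24 ± 0.16 (adjusted p = 1.82e-15 and 1.01e-18). Interferon-stimulated genes had 36 of 41 down and 5 not passing, with 39 down adjusted over the list alone (median -1.93, or -1.91 with bounds, adjusted p = 1.97e-56). Early response genes had 9 of 18 down and 9 not passing, with 11 down adjusted over the list alone (median -1.39, or -1.18 with bounds, adjusted p = 3.08e-10). Antigen presentation genes had 18 of 23 down and 5 not passing, with 1 up and 20 down adjusted over the list alone (median -0.93, or -0.85 with bounds, adjusted p = 1.59e-18). Cell cycle genes had 25 of 36 down and 11 not passing, with 1 up and 27 down adjusted over the list alone (median -0.29, adjusted p = 3.89e-10). These 4 calls held with an estimated correlation. Glycolysis and hypoxia genes had 1 of 25 up, 14 down and 10 not passing, with 2 up and 14 down adjusted over the list alone (median -0.33, adjusted p = 0.00014, adjusted p = 0.181 with an estimated correlation). Steep length trends in libraries P and R of the knockout fall on 1 side of this comparison.

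The interaction for the SGK1 knockout (SGK1KO difference in DMXAA response) counted 517 genes, 318 up and 199 down. It was 80 in a fit of the groups compared alone, 298 without a filter, 894 with DESeq2, 879 with the length and GC trend removed and 210 without the steep libraries, with 1 knockout library at rest left. The count was 309 and 244 without control rest libraries A and B, 339 without control DMXAA library M, and 1499 and 266 without SGK1 knockout rest libraries D and F. Cd33 (ENSMUSG00000004609.12, chromosome 7, 43173640 to 43193852), which encodes a sialic acid receptor, had a higher log2 fold change in the knockout by 1.52 ± 0.15 (adjusted p = 2.37e-08), going from 64.5 to 154 CPM against 29.1 to 24.1 CPM in control cells. Irf7 had a lower one (-2.31 ± 0.32, adjusted p = 2.16e-05), going from 14.3 ± 3.86 to 3.80 ± 0.687 CPM against 84.1 ± 1.74 to 111 ± 11.4. The interaction was negative for cell cycle genes, with 3 of 36 down, none up and 33 not passing, and 9 down adjusted over the list alone (median -0.18, adjusted p = 1.97e-07), a call that held with an estimated correlation. Interferon-stimulated genes had 2 of 41 up, 13 down and 26 not passing, with 2 up and 17 down adjusted over the list alone (median -0.51, adjusted p = 1.12e-08, adjusted p = 0.208 with an estimated correlation). The early response list had a median of 0.14 with bounds, but its direction turned with limma on TPM, so no direction is drawn from it.

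The double knockout was compared with control cells at rest (n = 3 and 3, b2) for how the line edited at both genes differed. The count was 1150 genes, 502 up and 648 down, against 527 in a fit of the groups compared alone and 757 without double knockout rest library H. Crlf2, which encodes a cytokine receptor chain, was at least 147-fold lower, Plod2 at least 54.1-fold lower, Btg3 at least 38.8-fold lower, and Zfp334 at least 34.5-fold higher. Rtp4 fell by 5.51 ± 0.27 and Cmpk2 fell by 5.94 ± 0.37 (adjusted p = 3.07e-18 and 3.88e-15). Interferon-stimulated genes had 37 of 41 down and 4 not passing, with 41 down adjusted over the list alone (median -2.55, or -2.25 with bounds, adjusted p = 5.36e-108). In the early response list, 11 of 18 were down and 7 did not pass, with 14 down adjusted over the list alone (median -2.43, adjusted p = 9.13e-27). The endoplasmic reticulum unfolded protein response list had 12 of 20 down and 8 not passing, with 13 down adjusted over the list alone (median -0.39, adjusted p = 2.11e-15). Macrophage identity genes had 1 of 27 up, 7 down and 19 not passing, with 2 up and 13 down adjusted over the list alone (median -0.21, adjusted p = 2.96e-08), among them Adgre1, which encodes F4/80, at -1.47 ± 0.15 (adjusted p = 8.94e-10). FOXO target genes had 4 of 27 up and 23 not passing, with 6 up adjusted over the list alone (median 0.15, adjusted p = 0.0066). All 5 calls held with an estimated correlation. Osteoclast markers had 4 of 16 up, 3 down and 9 not passing, with 5 up and 3 down adjusted over the list alone (median 0.23, or 0.10 with bounds, adjusted p = 0.0277), a call that ended without control rest library A (0.0539) or C (0.0569).

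With DMXAA the double knockout was compared with control cells in both batches (n = 5 and 5 in b1, n = 3 and 4 in b2). The mean of the batches gave 4636 genes, 2264 up and 2372 down, of which 284 and 644 changed at least 2-fold. In b1 alone 2453 genes passed (1312 up, 1141 down) and in b2 alone 3960 (1833 up, 2127 down), and the batches differed in 1340 genes. Maoa was at least 159-fold higher, Plod2 at least 90.2-fold lower and Crlf2 at least 66.0-fold lower. Bdh1 was at 0.0214 CPM against 10.6 in b1 and at 0 against 8.02 in b2. Rsad2 fell by 5.16 ± 0.20 (adjusted p = 1.52e-21), with 42.5 ± 9.51 CPM against 1670 ± 130 in b1 and 9.87 ± 1.6 against 319 ± 65.6 in b2. Ifnb1, chosen after its values were seen, fell by 3.87 ± 0.43 (adjusted p = 6.19e-08), with 2.54 CPM against 37.7 in b1 and 0.999 against 14.3 in b2. Oas1a fell by 2.52 ± 0.09 (adjusted p = 9.32e-26). The FOXO target genes had a median of only 0.11 with bounds (0.0539 in b1 and 0.0758 in b2), and among them S1pr1 rose by 2.50 ± 0.25 (adjusted p = 8.59e-11). Ndrg1 (ENSMUSG00000005125.14, chromosome 15, 66801167 to 66841489), whose protein is a substrate of SGK1, rose by 0.64 ± 0.09 (adjusted p = 1.92e-07), with 24.9 ± 2.64 CPM against 18.8 ± 1.95 in b1 and 23.5 ± 2.62 against 12.7 ± 2.34 in b2.

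The early response list had 15 of 18 genes down in the double knockout with DMXAA, none up and 3 not passing, with 17 down adjusted over the list alone (median -2.41, or -1.76 with bounds, adjusted p = 2.29e-20; -2.33 in b1 and -2.36 in b2, or -2.02 and -1.89 with bounds). Interferon-stimulated genes had 40 of 41 down and 1 not passing, with 41 down adjusted over the list alone (median -2.27, or -2.23 with bounds, adjusted p = 2.83e-69; -2.14 in b1 and -2.40 in b2, the latter -2.33 with bounds). Antigen presentation genes had 21 of 23 down and 2 not passing, with 1 up and 21 down adjusted over the list alone (median -0.71, adjusted p = 2.29e-20; -0.61 and -0.86, the latter -0.84 with bounds). Glycolysis and hypoxia genes had 18 of 25 down and 7 not passing, with 19 down adjusted over the list alone (median -0.31, adjusted p = 7.92e-12; -0.25 and -0.42, the latter -0.38 with bounds). Osteoclast markers had 9 of 16 up, 2 down and 5 not passing, the same numbers adjusted over the list alone (median 0.28, or 0.25 with bounds, adjusted p = 0.00172; 0.17 and 0.53, the latter 0.41 with bounds), with Atp6v0d2 up by 3.61 ± 0.33 (adjusted p = 4.5e-12). These 5 calls held with an estimated correlation and in each batch. Cell cycle genes had 23 of 36 down and 13 not passing, with 25 down adjusted over the list alone (median -0.21, adjusted p = 6.03e-10), but the list was not called in b1 alone (adjusted p = 0.0762).

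The interaction for the double knockout (dKO difference in DMXAA response, b2) counted 542 genes, 304 up and 238 down. It was 134 in a fit of the groups compared alone, 847 with DESeq2, 360 with limma on TPM and 952 with the length and GC trend removed. The count was 338 without double knockout rest library I and 356 without control rest library C. Cd33 had a higher log2 fold change in the double knockout by 1.90 ± 0.16 and Ndrg4 by 1.37 ± 0.12 (adjusted p = 5.11e-11 for each), Cd33 going from 56.8 to 176 CPM and Ndrg4 from 58.1 to 139 CPM against 29.1 to 24.1 and 18.3 to 17 CPM in control cells. Spp1, which encodes osteopontin, had a lower one (-1.53 ± 0.21, adjusted p = 1.15e-05). The interaction was negative for cell cycle genes, with 11 of 36 down, none up and 25 not passing, and 21 down adjusted over the list alone (median -0.33, adjusted p = 5.2e-16). It was positive for sterol synthesis and SREBP2 targets, with 6 of 24 up, none down and 18 not passing, and 11 up adjusted over the list alone (median 0.24, adjusted p = 1.25e-09). Both calls held with an estimated correlation. Of early response genes, 4 of 18 were up and 14 not passing, with 5 up adjusted over the list alone (median 0.23, adjusted p = 0.0172, adjusted p = 0.404 with an estimated correlation). That call (list interferon and IRF3 early response, dKO difference in DMXAA response) ended without control DMXAA library K (0.0541) or double knockout libraries U (0.0695) or H (0.118), and turned with limma on TPM (0.00776).

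Control cells with inhibitor and DMXAA were compared with control cells with DMXAA (n = 5 and 5, b1), which asks for the effect of the inhibitor in cells with unedited SGK genes. The count was 1566 genes, 677 up and 889 down, against 2859 in a fit of the groups compared alone and 2633 without the steep libraries of b2. Rsad2 fell from 1670 ± 130 to 352 ± 58.8 CPM (-2.25 ± 0.21, adjusted p = 6.7e-10), and Irgm1, which encodes an interferon-inducible GTPase, fell from 203 ± 10.8 to 59.6 ± 7.56 CPM (-1.76 ± 0.10, adjusted p = 1.21e-16). Ifnb1, chosen after its values were seen, was at 7.06 CPM against 37.7 (-2.42 ± 0.48, adjusted p = 0.00118). Cgas fell by 0.54 ± 0.05 (adjusted p = 4.52e-10). Cass4 rose from 7.81 to 25 ± 2.53 CPM (1.68 ± 0.16, adjusted p = 9.53e-11), and the FOXO target genes Sesn1 and Txnip rose by 0.97 ± 0.08 and 0.66 ± 0.05 (adjusted p = 6.99e-12 and 1.98e-12). The early response list had 14 of 18 down, none up and 4 not passing, with 16 down adjusted over the list alone (median -1.95, adjusted p = 4.26e-32). Interferon-stimulated genes had 35 of 41 down and 6 not passing, with 38 down adjusted over the list alone (median -0.98, adjusted p = 5.47e-58). Immediate early genes had 2 of 25 up, 10 down and 13 not passing, with 4 up and 15 down adjusted over the list alone (median -0.62, adjusted p = 8.99e-07). NF-kB and inflammatory cytokines had 1 of 31 up, 7 down and 23 not passing, with 1 up and 11 down adjusted over the list alone (median -0.40, adjusted p = 1.72e-05). Cell cycle genes had 15 of 36 down and 21 not passing, with 17 down adjusted over the list alone (median -0.15, adjusted p = 7.34e-13). These 5 calls held with an estimated correlation. By fry, the early response list moved down on balance (adjusted p = 4.93e-12). FOXO target genes had 6 of 27 up, 3 down and 18 not passing, with 10 up and 4 down adjusted over the list alone (list FOXO target genes, Inhibitor vs none in WT with DMXAA; median 0.0026, adjusted p = 0.0225, and 0.0523 in a fit of the groups alone).

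**Figure D3:**
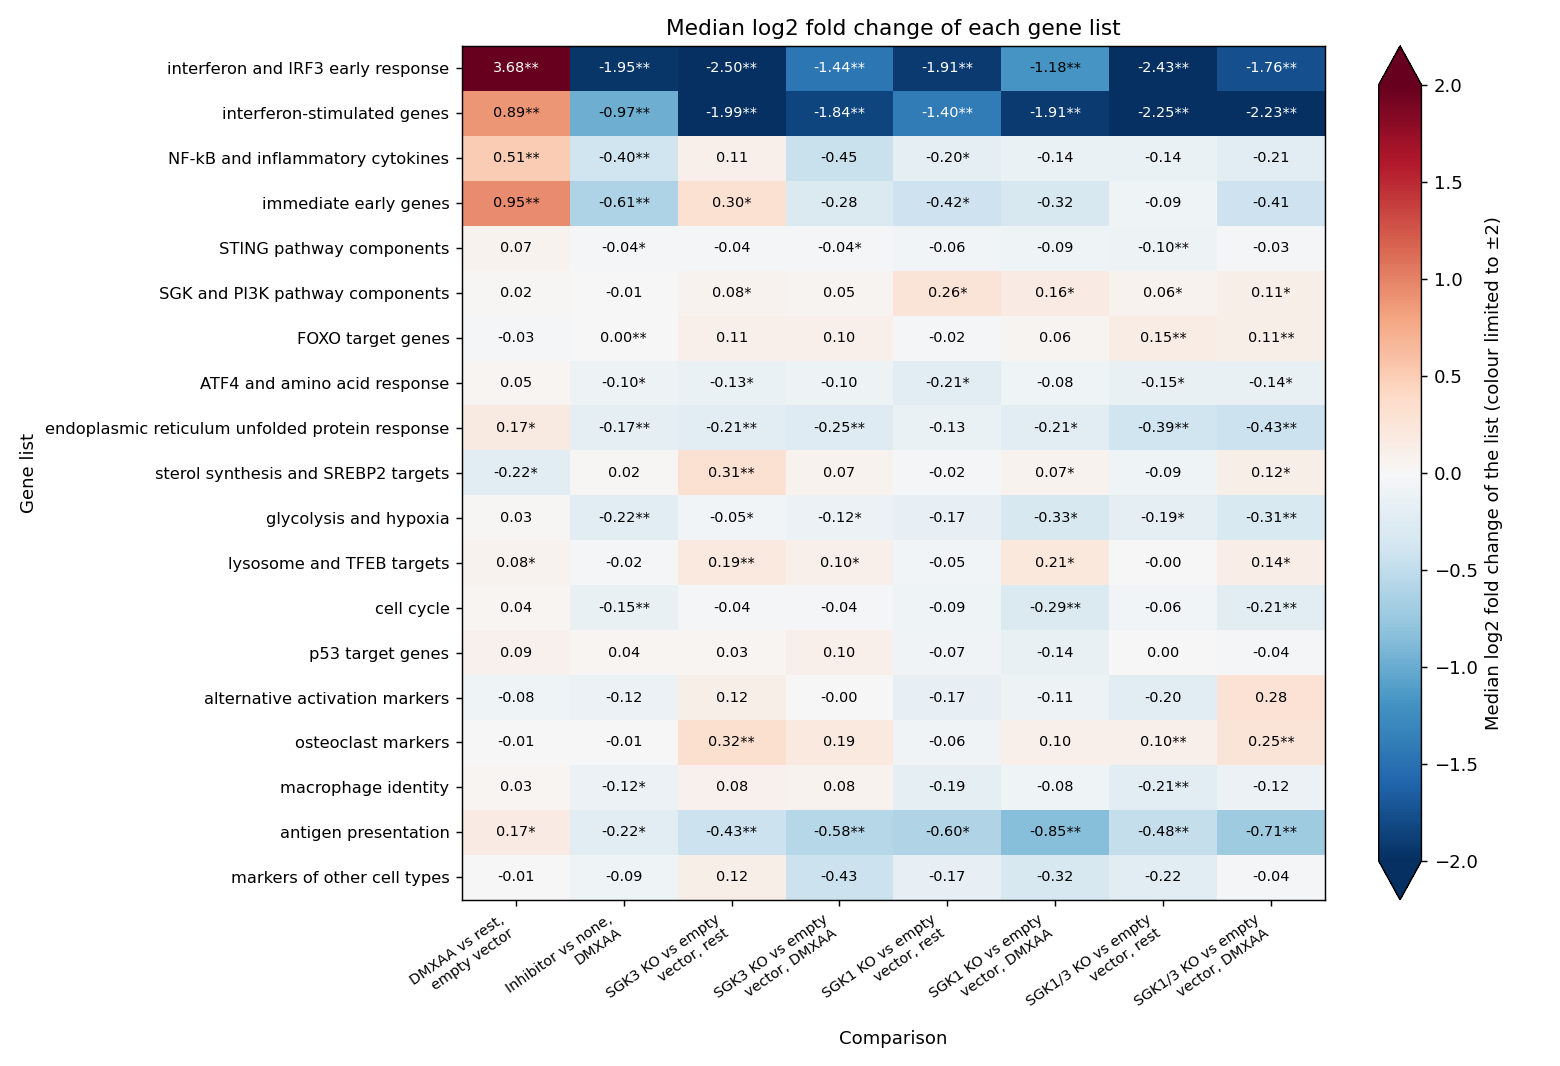
Median log2 fold change of each gene list (vertical axis) in each comparison (horizontal axis), with genes at 0 held at their bounds and colour limited to 2 either way; * marks a camera call with the preset correlation and ** one that also held with an estimated correlation. With DMXAA, the early response medians were -1.44 in the SGK3 knockout, -1.76 in the double knockout and -1.95 with inhibitor.

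The double knockout was compared with the SGK3 knockout with DMXAA (n = 5 and 5, b1) for how lines with 1 and 2 edited genes differed. The comparison dKO vs SGK3KO with DMXAA gave 396 genes, 138 up and 258 down, against 837 in a fit of the groups compared alone and 659 without the steep libraries of b2. Sgk1 fell by 2.17 ± 0.32 (adjusted p = 1.16e-05). Trp53i11 fell by 5.25 ± 0.10 (adjusted p = 4.99e-35), at 0.846 CPM against 32.1, and Jam2, which encodes a junctional adhesion molecule, was higher by 4.41 ± 0.13 (adjusted p = 3.39e-28), at 18 CPM against 0.849. Tmem176b fell by 2.75 ± 0.10 (adjusted p = 1.8e-25). Control cells had 61.3 CPM of Trp53i11 and 19.2 of Jam2. Trp53i11 was higher in the double knockout of b2, as given in the next paragraph, so its level in this line was not the same in both batches. The cause was not tested. Interferon-stimulated genes had 6 of 41 down and 35 not passing, with 15 down adjusted over the list alone (median -0.28, adjusted p = 1.21e-13, adjusted p = 0.0569 with an estimated correlation). Osteoclast markers were called up with 2 of 16 up and 14 not passing, 3 up adjusted over the list alone and a median of -0.0085, opposite in sign to the test (adjusted p = 0.00954).

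The double knockout was compared with the SGK1 knockout with DMXAA (dKO vs SGK1KO with DMXAA, n = 3 and 4, b2) for the same question from the other single knockout. It gave 1218 genes, 577 up and 641 down, against 58 in a fit of the groups compared alone, 2007 with the length and GC trend removed and 1622 without double knockout library X. Sgk1 did not differ past the threshold (-0.79 ± 0.40, adjusted p = 0.243). Tmem176b fell by 2.59 ± 0.12 and Trp53i11 fell by 2.14 ± 0.10 (adjusted p = 2.59e-20 and 6.47e-20), at 19.7 CPM against 118 and 13 against 57.4. Slc6a8, which encodes a creatine transporter, was higher by 1.75 ± 0.13 (adjusted p = 2.36e-13), at 32.9 ± 2.58 CPM against 9.80 ± 1.85. Early response genes had 5 of 18 down and 13 not passing, with 9 down adjusted over the list alone (median -0.79, adjusted p = 9.16e-07, adjusted p = 0.0579 with an estimated correlation). Osteoclast markers had 4 of 16 up, 1 down and 11 not passing, with 7 up and 1 down adjusted over the list alone (median 0.42, adjusted p = 0.000429), and held with an estimated correlation.

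The lists for alternative activation and for markers of other cell types were called in none of the 16 comparisons. In the DMXAA response of control cells, alternative activation had 2 of 14 genes up and 12 not passing, the same adjusted over the list alone (median -0.08, adjusted p = 0.996). Markers of other cell types had 1 of 19 up and 18 not passing, the same adjusted over the list alone (median 0.20, or -0.0131 with bounds, adjusted p = 0.813). Only 2 of 9 listed B cell markers, Cd79a and Ighm, were tested, and they summed to between 114 and 250 CPM in the group means of both batches. In b2 with DMXAA the sum was 124 ± 10.2 CPM in control cells, 184 ± 10.9 in the SGK1 knockout and 156 ± 7.68 in the double knockout. In b1 with DMXAA it was 226 ± 4.68 CPM in control cells, 250 ± 12.2 in the double knockout, 216 ± 7.15 in the SGK3 knockout and 212 ± 7.58 with inhibitor. With DMXAA, Ighm was higher in the SGK1 knockout (0.56 ± 0.05, adjusted p = 5.68e-11) and the double knockout (0.24 ± 0.04, adjusted p = 2.37e-06), and at rest it was lower in the SGK3 knockout (adjusted p = 0.0216). The 6 dendritic cell markers tested summed to 5.45 ± 1.13 CPM in the double knockout with DMXAA against 2.13 ± 0.421 in control cells of b1. In b2 they summed to 3.37 ± 0.892 against 1.43 ± 0.548. The T cell marker Lck was at 1.92 ± 0.243 CPM against 3.84 ± 0.39 in b1 and 1.33 ± 0.359 against 1.96 ± 0.488 in b2.

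Genes responsive to DMXAA by at least 2-fold in the control cells of one batch were followed in the other, so that no control libraries were shared. Of 271 genes induced in b2, 69 were lower and 19 higher in the SGK3 knockout with DMXAA in b1 (median -0.31, adjusted p = 8.67e-09), 89 and 14 in the double knockout (median -0.46, adjusted p = 2.14e-14) and 104 and 3 with inhibitor (median -0.48, adjusted p = 1.17e-30). These 3 calls held with an estimated correlation. Of 615 genes induced in b1, 100 were lower and 76 higher in the SGK1 knockout with DMXAA in b2 (median 0.0052, adjusted p = 0.552), and 126 and 43 in the double knockout (median -0.15, adjusted p = 0.00439, adjusted p = 0.271 with an estimated correlation). Of 84 genes repressed in b2, 24 were higher and 1 lower in the SGK3 knockout (median 0.54, adjusted p = 8.17e-11), 26 and 3 in the double knockout (median 0.55, adjusted p = 1.23e-11) and 14 and 1 with inhibitor (median 0.41, adjusted p = 1.13e-07). Of 363 genes repressed in b1, 41 were higher and 21 lower in the SGK1 knockout (median 0.06, adjusted p = 0.0803), and 74 and 15 in the double knockout (median 0.32, adjusted p = 1.42e-06). All but that of the SGK1 knockout were calls and held with an estimated correlation. With a limit of 4-fold, the call for repressed genes ended with inhibitor (27 genes, median 0.17, adjusted p = 0.254). In the double knockout of b2 it then held (75 genes, adjusted p = 0.00511) but not with an estimated correlation (adjusted p = 0.0709). Across batches, the inhibitor and the double knockout of b2 shared 298 genes higher and 422 lower, where independence would give 67.8 and 103, with a Pearson correlation of 0.0958 and a Spearman correlation of 0.186 across 18315 genes (Pearson 0.313 over genes of at least 5 CPM). The SGK3 and SGK1 knockouts shared 431 higher and 394 lower against 106 and 98.5 (Pearson 0.17, and 0.562 at 5 CPM). Their Spearman correlations were lower, at 0.141, and 0.211 at 5 CPM. At 5 CPM they shared 374 higher and 313 lower against 146 and 117. The double knockout in b1 and b2 shared 712 higher and 662 lower against 131 and 133 (Pearson 0.353, and 0.791 at 5 CPM). The Spearman correlations of this pair were 0.304, and 0.452 at 5 CPM.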

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

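The tests of a uniformly weaker response, of the length trend in the SGK1 knockout with DMXAA, of line differences behind the interferon result and of the genes that changed most in all 3 knockout lines were chosen only after the results were seen.

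Lower interferon lists with DMXAA were seen in all 3 knockouts and in control cells with inhibitor. A length and GC trend between libraries is argued against as the whole cause, since with the trend removed the early response medians were -1.6 in the SGK3 knockout, -2.4 in the double knockout, -1.16 in the SGK1 knockout and -1.96 with inhibitor. With inhibitor, other induced genes matched for induction in b2 were lower too (median -0.603), and 12 early response genes lay below them by -1.34 (permutation p = 1e-05, the smallest possible with 100000 sets). This does not decide whether the DMXAA response was uniformly weaker. The inhibitor was given in b1, where the early response list was induced more than in b2 (median 4.54 against 2.71 with bounds), and induction in b1 was not matched. The permutation also treats genes as independent, and no inhibitor group at rest was measured. In the SGK3 and double knockouts a uniformly weaker response stays open too. The same gaps were -0.98 in the SGK3 knockout and -1.26 in the double knockout of b1 (permutation p = 0.00028 and 0.00044). But levels with DMXAA also hold the lower levels at rest, and the early response median of the interaction was 0.27 in the SGK3 knockout. No such gap was computed for the SGK1 knockout. There the 615 genes induced in b1 were not lower as a set with DMXAA (median 0.0052, camera adjusted p = 0.552). The early response and interferon-stimulated medians were -1.18 and -1.91 with bounds. Induced genes were thus not uniformly lower in that line, though levels at rest enter these values too. Differences between lines unrelated to SGK cannot explain the inhibitor part, where 1 line was used and the median was -1.95. For the knockout part they cannot be told apart from loss of SGK, because the labels name 1 line per genotype. A set of 11 genes outside the interferon lists changed by at least 4 on the log2 scale in all 3 lines, but it does not decide, and it is not wholly separate from the interferon pattern. Off-target effects of the inhibitor were not tested.

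The count for the SGK1 knockout at rest, 4760 genes, coincided with steep length trends in libraries E and F. With the length and GC trend removed it was 2599, or 54.6%, of which 1782 genes were among the 4760 with the same direction, so part of the count may stem from library preparation. In a fit of the groups compared alone it was 255, so much of the count may also rest on the spread shared with other groups. The remainder of the count stays open. Without the steep libraries, E and F included, it was 653, with 1 knockout library at rest left. Without 1 library the count was 1927 (control B), 3143 (SGK1 knockout E) or 1879 (SGK1 knockout F) for SGK1KO vs WT at rest.

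With DMXAA, Maoa was higher, and Adgrl2, AI504432, Apol9a, Arl4c, Ifi44l, Lgals9, Nid2, Nsd1, Plod2 and Sdc3 were lower, by at least 4 on the log2 scale in all 3 knockout lines than in control cells. Not all were silent, since Ifi44l was at 11 CPM in the SGK3 knockout, and Apol9a and Ifi44l rose with DMXAA in control cells of b1, from 8.3 to 81.6 and from 70.4 to 227 CPM. With the length and GC trend removed, 100% of the 11 genes passed in all 3 comparisons. This is no test of the trend, because the genes were chosen for passing with changes of at least 4. The steepest trend in b2 was 0.37 per doubling of transcript length, too small for its removal to undo such changes. The inhibitor moved the 11 genes by a median of 0.505 in the direction of the knockouts, and 4 of them, Apol9a and Ifi44l included, passed with it. The inhibitor was compared with the same b1 control libraries that helped to select the genes, so part of this shift may be built in. Whether longer loss of SGK or a difference between the control line and the edited lines is the source cannot be told apart. No other explanation was tested.

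Other splits of the same libraries were counted in fits of the groups compared alone. Among DMXAA responses, the splits argue against chance in control cells (4756 genes, highest other split 1951), the SGK3 knockout (5323, 1) and the SGK1 knockout (751, 2). With DMXAA they do so for the SGK3 knockout (3480, 1), SGK1 knockout (1556, 0) and double knockout (4759, 960) against control cells. They also do so for the inhibitor (2859, 1) and for the double knockout against the SGK3 knockout (837, 3). In each of these comparisons 1 split, the real one, gave as many genes. Chance is not excluded, since only 35 to 56 splits were fitted for each, with no correction over comparisons. Nor can regrouping exclude chance differences between single lines or cultures, since the labels do not say that replicates were separate cultures. For the interactions the splits do not tell for or against chance, because labels exchanged in one arm alone turn a genotype effect into an interaction. Their real and highest other counts were 157 and 1220 in the SGK3 knockout, where 2 of 50 splits gave as many genes and the other one exchanged 4 of 5 genotype labels among the DMXAA libraries, 80 and 2 in the SGK1 knockout, and 134 and 2 in the double knockout. The splits do not argue against chance for the double knockout against the SGK1 knockout, where 2 of 35 splits reached the real 58. The highest other split gave 1662 with the steep libraries P, R and X on one side, which points to a structure of the samples. The splits are too few for the DMXAA response of the double knockout (477, highest other 0) and for the SGK3 (2316, 1), SGK1 (255, 0) and double knockout (527, 0) at rest.

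Single libraries stood apart from their group in 4 of 72 tests, close to the 1 in 20 that chance gives. These were Malat1 and Neat1 at 0.0395% in SGK3 knockout DMXAA library 5 (others 0.0231 to 0.0271), ribosomal RNA at 3.49% in SGK3 knockout DMXAA library 3 (0.515 to 0.625), Sgk1 at 25.4 CPM in control DMXAA library K of b2 (37.3 to 39.4), and Sgk3 at 120 CPM in double knockout DMXAA library 2 of b1 (others 117). DMXAA responses differed from that of control cells in 36 genes in the SGK3 knockout, 517 in the SGK1 knockout and 542 in the double knockout. These counts do not rank the lines, since fits of the groups compared alone gave 157, 80 and 134. The list medians were -0.549 for immediate early genes and -0.207 for sterol synthesis in the SGK3 knockout, -0.177 for the cell cycle in the SGK1 knockout, and 0.24 for sterol synthesis and -0.328 for the cell cycle in the double knockout. In b3, control library J, whose title and treatment field conflict, had 12.3 CPM of Ifnb1 against 0 in control cells at rest, and 538 of 665 induced genes lay nearer the stimulated mean.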

How the results depend on the processing

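The settings with the length and GC trend removed, without the steep libraries, with counts divided by 4, with a dispersion trend from estimateDisp, and with a replicate block together with the trend removed were chosen only after the results were seen. For each moved or reversed result below, the cause was not tested unless a trend is named.

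Fits of the groups compared alone gave 5323 genes for DMXAA response in SGK3KO, 751 for DMXAA response in SGK1KO, 477 for DMXAA response in dKO, 2316 for SGK3KO vs WT at rest, 3480 for SGK3KO vs WT with DMXAA, 157 for SGK3KO difference in DMXAA response, 255 for SGK1KO vs WT at rest, 1556 for SGK1KO vs WT with DMXAA, 80 for SGK1KO difference in DMXAA response, 527 for dKO vs WT at rest, 134 for dKO difference in DMXAA response, 2859 for Inhibitor vs none in WT with DMXAA, 837 for dKO vs SGK3KO with DMXAA and 58 for dKO vs SGK1KO with DMXAA. Reversed were Sgk3, DMXAA response in dKO (0.0187) and list interferon-stimulated genes, SGK3KO difference in DMXAA response (adjusted p = 0.649). Counts of comparisons within b1 were all higher in these fits than in the joint fit, and those within b2 all lower. The joint fit gives each gene 1 spread over both batches. Replicates were less alike in b2 (Spearman 0.959 to 0.977) than in b1 (0.979 to 0.986). The joint fit may therefore understate the spread of b2, and its adjusted p-values for b2 comparisons may be too small.

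With RLE factors, Sgk3, DMXAA response in dKO was 0.0105 and Sgk3, SGK1KO vs WT at rest was 0.0195. DESeq2 gave 0.0108 and 0.0196 for these, and 103, 894 and 847 genes for SGK3KO difference in DMXAA response, SGK1KO difference in DMXAA response and dKO difference in DMXAA response. Without a filter, SGK1KO difference in DMXAA response gave 298. With counts divided by 4, Sgk3, DMXAA response in dKO was 0.0112 and Sgk3, SGK1KO vs WT at rest was 0.00574.

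On TPM with limma, SGK3KO difference in DMXAA response gave 81 genes and dKO difference in DMXAA response 360. Reversed were Sgk3, DMXAA response in SGK1KO (-0.137), Sgk3, DMXAA response in dKO (0.00668), Sgk3, SGK1KO vs WT at rest (0.238) and Sgk3, SGK1KO vs WT with DMXAA (0.0465). The list interferon-stimulated genes, DMXAA response in SGK1KO (adjusted p = 0.725) and list interferon-stimulated genes, SGK3KO difference in DMXAA response (2.61e-09) turned, as did list interferon and IRF3 early response, SGK3KO difference in DMXAA response (1.44e-08), list interferon and IRF3 early response, SGK1KO difference in DMXAA response (0.576) and list interferon and IRF3 early response, dKO difference in DMXAA response (0.00776).

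With b3 added, SGK1KO vs WT with DMXAA gave 2373 genes and list cell cycle, dKO vs SGK1KO with DMXAA turned (adjusted p = 0.582). In b1 alone dKO vs WT with DMXAA gave 2453 genes. In b2 alone DMXAA response in WT gave 1443, and Sgk3, dKO vs WT with DMXAA was -0.00554.

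With the length and GC trend removed, counts were 92 for SGK3KO difference in DMXAA response, 2599 for SGK1KO vs WT at rest, 879 for SGK1KO difference in DMXAA response, 952 for dKO difference in DMXAA response and 2007 for dKO vs SGK1KO with DMXAA. Reversed were Slc7a11, SGK1KO vs WT at rest (-0.0281), Edem1, SGK1KO vs WT with DMXAA (-0.0249), Sgk3, dKO vs WT at rest (-0.00351), list SGK and PI3K pathway components, SGK1KO vs WT at rest (adjusted p = 0.379) and list SGK and PI3K pathway components, SGK1KO vs WT with DMXAA (0.839). Replicate numbers do not pair the samples: 57 pairs of the same number had residual correlations of -0.488 to 0.35. A replicate block gave counts within 1.5 times, and 85 for SGK3KO difference in DMXAA response with the trend also removed.

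Without the steep libraries of b2, counts were 1987 for DMXAA response in SGK1KO, 1359 for SGK3KO vs WT at rest, 3050 for SGK3KO vs WT with DMXAA, 113 for SGK3KO difference in DMXAA response, 653 for SGK1KO vs WT at rest, 2300 for SGK1KO vs WT with DMXAA, 210 for SGK1KO difference in DMXAA response, 2633 for Inhibitor vs none in WT with DMXAA and 659 for dKO vs SGK3KO with DMXAA. The SGK1 knockout then kept 1 library at rest (D), so its counts at rest and for its response take their spread from other groups. Reversed were Myc, DMXAA response in SGK1KO (0.491), Sgk1, SGK1KO difference in DMXAA response (0.58), Sgk3, dKO vs WT at rest (-0.00259) and Sgk3, dKO vs SGK1KO with DMXAA (-0.0442).

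Leaving out 1 library moved SGK3KO difference in DMXAA response to 23 (WT_rest 3), 22 and 20 (SGK3KO_rest 1 and 2) and 23 (SGK3KO_DMXAA 5), dKO vs WT at rest to 757 (dKO_rest H), dKO difference in DMXAA response to 338 (dKO_rest I) and 356 (WT_rest C), SGK1KO difference in DMXAA response to 309, 244, 339, 1499 and 266 (WT_rest A, WT_rest B, WT_DMXAA M, SGK1KO_rest D, SGK1KO_rest F), SGK1KO vs WT at rest to 1927, 3143 and 1879 (WT_rest B, SGK1KO_rest E, SGK1KO_rest F), and DMXAA response in SGK1KO to 2790 (SGK1KO_rest F). It reversed list interferon-stimulated genes, SGK3KO difference in DMXAA response (adjusted p = 0.0216, 0.925 and 0.977 without WT_rest 1, WT_DMXAA 1 and SGK3KO_rest 1) and list interferon-stimulated genes, DMXAA response in SGK1KO (0.934, SGK1KO_rest F). For genes it reversed Sgk3, DMXAA response in dKO (0.113 without T, 0.039 without H), Sgk3, dKO difference in DMXAA response (0.0577, T), Sgk3, dKO vs SGK1KO with DMXAA (-0.0721, X), Sgk3, SGK1KO difference in DMXAA response (0.00445 and 0.0331, WT_rest A and F), Sgk3, DMXAA response in SGK1KO (-0.00321, -0.018 and -0.0121, D, P and E), Sgk3, SGK1KO vs WT at rest (0.0375, E) and Sgk1, SGK1KO difference in DMXAA response (0.372, F). The far ends of the ranges over single libraries were 41 for SGK3KO difference in DMXAA response (WT_DMXAA 1), 766 for dKO difference in DMXAA response (dKO_DMXAA T), 966 for dKO vs WT at rest (dKO_rest G), 6051 for SGK1KO vs WT at rest and 5377 for DMXAA response in SGK1KO (both SGK1KO_rest D). For lists they were adjusted p = 0.00863 for list interferon-stimulated genes, SGK3KO difference in DMXAA response (WT_rest 2) and 0.694 for list interferon-stimulated genes, DMXAA response in SGK1KO (SGK1KO_rest E). For genes they were -0.126 for Sgk3, DMXAA response in dKO and -0.181 for Sgk3, dKO difference in DMXAA response (both X), 0.167 for Sgk3, dKO vs SGK1KO with DMXAA (T), -0.0701 for Sgk3, SGK1KO vs WT at rest and 0.0954 for Sgk3, DMXAA response in SGK1KO (both F), and -1.87 for Sgk1, SGK1KO difference in DMXAA response and -0.0744 for Sgk3, SGK1KO difference in DMXAA response (both E).

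For genes responsive at 4-fold in the other batch, the share higher was 7.24% of induced genes in the SGK1 knockout, 2.21% of induced and 18.5% of repressed genes in the double knockout of b1, 3.9% of induced genes in that of b2, and 0% of induced and 7.41% of repressed genes with inhibitor. The share lower among repressed genes was 0% in the SGK3 knockout, 9.33% in the SGK1 knockout, 0% in the double knockout of b1 and 0% with inhibitor. Among genes of at least 5 CPM, Pearson correlations were 0.313 for inhibitor and double knockout of b2 and 0.562 for SGK3 and SGK1 knockouts. They were 0.791 for the double knockout of b1 and b2 and 0.648 for SGK3 knockout and double knockout of b2. For SGK1 knockout and double knockout of b1 the value was 0.643. The Spearman correlations of these pairs, in the same order, were 0.294, 0.211, 0.452, 0.407 and 0.223.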

Other observations

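The prediction for the carry-over of resting levels was written before its result was seen, and no test in this part was chosen afterwards.

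As a hypothesis, interferon-stimulated genes could be lower with DMXAA in the knockouts because their lower level at rest carries over. A full carry-over would leave the median log2 fold change with DMXAA at least as low as at rest in all 3 knockouts, and without it the median with DMXAA would lie above that at rest by more than 0.5 in all 3. The medians with DMXAA minus those at rest were 0.302 in the SGK3 knockout, -0.513 in the SGK1 knockout and 0.154 in the double knockout of b2, or 0.154, -0.512 and -0.0809 with bounds for genes with a group at 0. Neither condition was met either way, so the test left the hypothesis open, and a test of nascent RNA or of cells with blocked interferon receptors at rest would be needed to separate it from a weaker response.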
